A study of Homo sapiens with 2 samples.

How the data were processed

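Open chromatin was profiled by Omni-ATAC-seq in SKBR3 cells, in 1 group of 2 replicates numbered as in the labels. Libraries were made from 50K cells each, per the labels' protocols. The aligner Bowtie2 2.2.4, the peak caller MACS2 2.1.1 and the hg19 build are named, per the submitters' processing notes. Peaks were called on each replicate by itself with MACS 2.1.1.20160309 in paired-end mode without a control library, at a q cutoff of 0.05, per the file headers. The same headers give an effective genome size of 2.7e+09 bases, a local window of 10 kb for the expected coverage, and at most 1 fragment kept at each position. Read trimming, removal of mitochondrial reads, blacklist filtering and any shift of read ends for the Tn5 cut are not given in the sources used here. In paired-end mode the caller piles up whole fragments, so pileup counts fragments that span a position and not transposase cuts, and a fragment over a nucleosome adds to it.

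The deposited peak lists hold the signal at each summit as pileup, a whole number of fragments after duplicate removal that is not scaled to depth. The deposited fold enrichment is a ratio, made by the authors' peak caller, of summit pileup plus 1 to local expected pileup plus 1. The −log10 p and −log10 q in the deposited lists come from the caller's Poisson test within each library. These values are the authors' own for each peak and were used to describe, rank and filter peaks within a list. Positions and widths in the deposited lists are in bases, counted from 1. Because no control library entered the calling, the expected coverage comes from the same library, and a peak inside a stretch of high coverage gets a lower fold than an equally tall peak elsewhere.

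The local expected pileup was recovered from the deposited columns as (pileup + 1) / fold enrichment − 1. The Poisson tail probability computed from it matched the deposited −log10 p to a relative difference of at most 6.18e-06 in replicate 1 and 6.94e-06 in replicate 2. It could not be compared at 31 and 42 peaks, where the computed probability was too small to represent. The lowest value, 1.17 and 1.40 fragments, is the background over the whole genome and was the value at 14.5% and 13.2% of peaks.

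Overlap was computed with bedtools 2.31.1 at a minimum of 1 base. Chance overlap came from 100 shuffles of one list between the start of each chromosome and its last peak, with assembly gaps not excluded. Shared peaks for the comparison of values were those that overlapped exactly 1 peak of the other list. Shares carry Wilson 95% intervals, which cover counting error only. Agreement was measured by Pearson r on log2(pileup + 1), Spearman rho and the SD of the log2 ratio. The spread of single peaks was set against simulated pairs of peaks whose summit is the point of highest coverage by Poisson numbers of fragments, and pileups summed by chromosome were compared by a chi-square test over 23 chromosomes. Peaks were summed in 1 Mb bins by summit position. A bin counted as raised when it held at least 5 peaks and its median local expected pileup was at least 3 times that of all peaks, in both replicates. Steps along a chromosome were placed between neighbouring peaks, with at least 8 peaks on each side, at the split that left the smallest sum of squared deviations of the log2 values. Peaks with no other peak within 10 kb are called isolated. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

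The scripts were tested on simulated data made from the 61782 peaks of replicate 1, for the comparison of the replicates. Of these, 79.9% were given a partner, and 79.9% were recovered as overlapped. Partners were moved by less than the width of the narrowest peak, so their overlap was certain and checks the code only. The median ratio of the simulated lists came out at 1.14 against the 1.15 they were made with. The 1 bin with raised coverage was the only bin called, with local expected pileups drawn independently for each peak.

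Depth, taken as the fragments read by the caller, was 17374207 and 20563304, of which 15574689 and 18418420 were kept after its removal of duplicates. Precision follows from pileup, since the median peak rests on 20 and 23 fragments. The named peaks follow a rule set before the data were examined: the 10 shared peaks of highest mean pileup, and the 5 shared peaks with the largest ratio in each direction among the peaks in the upper 75% of mean pileup. The bins of raised coverage, the steps, and their alternatives were chosen after the data were seen. Alternatives tried were a stricter list, a reciprocal overlap of 50%, other scales for the correlation, bins of 500 kb, peak number in place of pileup, other limits for raised bins, and each replicate alone.

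The gene table used here carries GRCh38 positions, and the peaks are on hg19. It was used only for the chromosomes of ERBB2, MAL2 and MYC, the last of which the text does not otherwise use, and no peak was assigned to a gene, promoter or exon. The planned shares of peaks by gene feature, the accessibility of gene lists, the parts of the naming rule that name genes, and the placing of named genes in bins were therefore not analysed here.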

Results

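SKBR3 is an established human breast cancer cell line, and the labels describe it as HER2 positive. HER2 is a receptor tyrosine kinase encoded by ERBB2, a gene on chromosome 17. The title of the series concerns HER2 and MAL2, a membrane protein of lipid rafts whose gene lies on chromosome 8. Open chromatin was measured by Omni-ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, with libraries of 50K cells each. The series held 1 group of 2 replicates with no treatment recorded. The labels do not say whether the replicates came from separate cultures, so the spread between them, and every p-value resting on it, may be technical. The peak caller read 17374207 fragments for replicate 1 and 20563304 for replicate 2, and any filtering before that step is not given. After removal of duplicates 15574689 and 18418420 fragments remained, a ratio of 1.18 between replicate 2 and replicate 1. The caller thus removed 10.4% of the fragments it read as duplicates in both libraries.

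The highest summed peak pileup in both replicates, uncorrected for local coverage, lay on chromosome 17 between 37 and 38 Mb (all positions are on hg19). This 1 Mb bin held 98 peaks in replicate 1 and 101 in replicate 2, which ranked 2 and 3 by number of peaks. Its summed summit pileup, the number of fragments over each peak's summit added over its peaks, was 36.8 and 36.9 times that of the median bin. It took 0.869% and 0.877% of all summit pileup and ranked 1 among the 2756 bins with a peak in either list. The next 4 bins by summed pileup lay on the same chromosome or on chromosome 8. Chromosome 8 between 124 and 125 Mb reached 26.4 and 28.2 times the median bin, between 128 and 129 Mb 23.9 and 23.5 times, and between 81 and 82 Mb 22.9 and 24.3 times. Chromosome 17 between 38 and 39 Mb reached 19.2 times the median bin in each replicate. By number of peaks alone the same 5 bins reached 5.38, 5.09, 5.02, 5.34 and 5.14 times the median bin, as means over both replicates in the order chromosome 17 from 37 Mb, chromosome 8 from 124, 128 and 81 Mb, and chromosome 17 from 38 Mb. In bins of 500 kb the bin of highest sum from 128 to 129 Mb on chromosome 8 reached 39.3 times the median bin.

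The same stretches carried a raised local expected pileup, the fragment coverage that the peak caller expected from a window of 10 kb around each summit. On chromosome 17 between 37 and 38 Mb its median was 20.1 fragments in replicate 1 and 25.1 in replicate 2, which is 9.25 and 9.62 times the median over all peaks of that replicate. In 13 bins the median was at least 3 times that of all peaks in both replicates, a limit set after the data were seen. Of these, 9 lay on chromosome 8, starting at 71, 81, 90, 120, 121, 122, 123, 124 and 128 Mb. The other 4 lay on chromosome 17, starting at 37, 38, 39 and 77 Mb. Off these chromosomes the highest bin differed between the replicates. It reached 2.70 times in replicate 1, on chromosome 20 from 48 Mb, and 2.81 times in replicate 2, on chromosome 7 from 1 Mb. The 13 bins held 1.63% and 1.73% of the peaks and 5.12% and 5.31% of the summed pileup. Peaks inside them were tall, with a median pileup of 44.5 and 48 fragments against 20 and 23 in the other bins. Their median fold enrichment over the local expected pileup was lower, at 4.22 and 3.99 against 6.44 and 6.42. Both differences follow in part from how the bins were picked. A high local expected pileup raises the pileup that a call needs and divides the fold. The relative local expected pileup of the bins was close in both replicates, with Pearson r = 0.972 and Spearman rho = 0.916 across the 2268 bins with at least 5 peaks in each replicate. Bins are not independent replicates, so no p-value was attached. At a limit of 2 times the number of bins was 58, on 12 chromosomes, and at 4 times it was 8. In bins of 500 kb it was 30, and from isolated peaks alone, with no other peak within 10 kb, it was 6. These 6 were all among the 13.

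**Figure D1:**
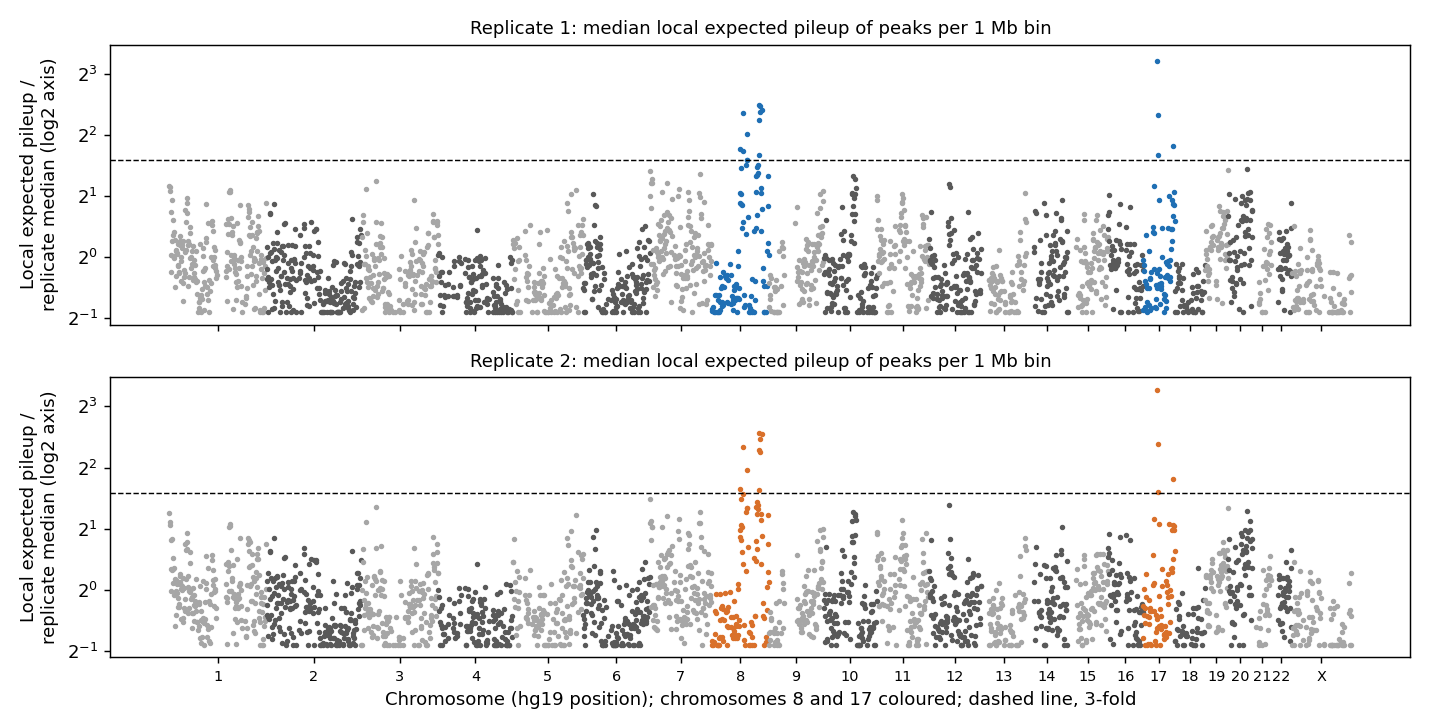
Median local expected pileup of the peaks in each 1 Mb bin (points), divided by the median over all peaks of that replicate (log2 axis), along chromosomes 1 to 22 and X, with replicate 1 above and replicate 2 underneath. The dashed line marks 3-fold, and the 13 bins that pass it in both replicates lie on chromosomes 8 and 17, with the bin of chromosome 17 from 37 Mb at 9.25 and 9.62.

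At a finer scale the raised stretch of chromosome 17 had steps at nearly the same positions in both replicates. The median local expected pileup rose from 1.85 to 26.9 fragments in replicate 1 and from 2.19 to 34.8 in replicate 2. The step lay between a peak ending at 37213510 and a peak starting at 37279810 in replicate 1, and between 37213326 and 37279752 in replicate 2. The local expected pileup fell again by a factor of 3.58 between 38776483 and 38803654 in replicate 1, and by 3.57 between 38776530 and 38803778 in replicate 2. A further stretch began between 39440972 and 39478547 and ended between 40562025 and 40575135 in replicate 1, with corresponding positions of 39440956 to 39478619 and 40561942 to 40580357 in replicate 2. On chromosome 8 the local expected pileup fell by a factor of 6.30 between 129089461 and 129100904 in replicate 1, and by 7.0 between 129094903 and 129103171 in replicate 2. A weaker fall on chromosome 8 was placed differently, by a factor of 3.31 between 124781250 and 124789117 in replicate 1 and by 2.77 between 124732598 and 124753065 in replicate 2. The search windows for these steps were chosen after the data were seen, and each position is no finer than the gap between neighbouring peaks. Among 200 kb windows of chromosome 17 from 34 to 42 Mb, the highest value lay between 37.8 and 38 Mb, where the median local expected pileup was 44.5 and 54.3 fragments and the median summit pileup 175 and 221.

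**Figure D2:**
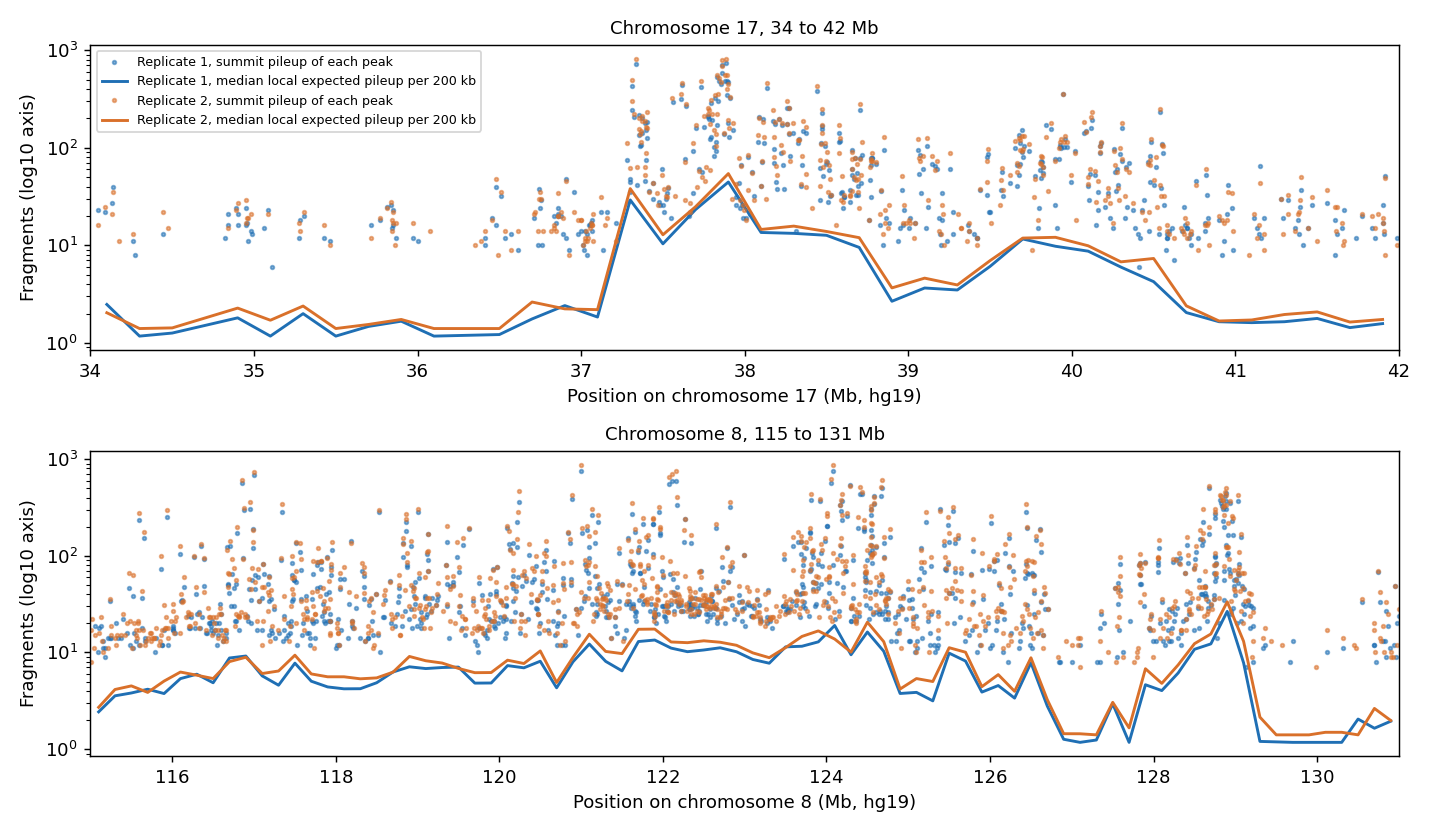
Summit pileup of each peak (points) and median local expected pileup per 200 kb window (lines), in fragments on a log10 axis, along part of chromosome 17 (upper panel) and of chromosome 8 (lower panel), with replicate 1 in blue and replicate 2 in orange. On chromosome 17 the lines rise from 1.84 and 2.19 in the window from 37 to 37.2 Mb to 29.2 and 38.1 in the next, and on chromosome 8 they fall from 26.6 and 33.4 between 128.8 and 129 Mb to 1.2 and 2.14 between 129.2 and 129.4 Mb.

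Of the 10 shared peaks with the highest mean pileup, 8 lay on chromosomes 8 and 17. On chromosome 17 they were the peaks from 37885890 to 37887322, with 777 ± 62.2 fragments (mean ± SD, n = 2), from 37333426 to 37334064, with 762.5 ± 60.1 (n = 2), and from 37861877 to 37862619, with 747.5 ± 58.7 (n = 2). On chromosome 8 the tallest was the peak from 124084460 to 124085393, with 812 ± 87.7 fragments (n = 2). It was followed by the peaks from 120994626 to 120995837, with 809.5 ± 72.8 (n = 2), and from 81665033 to 81666016, with 748 ± 69.3 (n = 2). The remaining peaks of chromosome 8 ran from 116999857 to 117000825, with 712 ± 32.5 (n = 2), and from 122157303 to 122158287, with 672.5 ± 103.9 (n = 2). Replicate 2, the deeper library, had the higher pileup at all 10 peaks, so the SDs of these unscaled values include the difference in depth. The tallest pair of the genome lay elsewhere, on chromosome 7 from 61968676 to 61969704, with 1014 ± 32.5 fragments (n = 2), and on chromosome 21 from 9826761 to 9827551, with 1004 ± 16.97 (n = 2). The local expected pileup was 63.2 and 67.5 fragments at the first and 122 and 129 at the second. Blacklist filtering is not given, so fragments from multi-copy sequences cannot be told apart from open chromatin at this pair. Peak ends are those of replicate 1. Peaks of at least 500 fragments numbered 28 in replicate 1, of which 18 lay on chromosome 8 and 5 on chromosome 17, and 34 in replicate 2, of which 21 and 8 lay there. Pileup is a raw fragment number that is not corrected for local coverage, and 19 of the 28 and 24 of the 34 tall peaks lay in the 13 bins of raised local expected pileup.

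Peak density differed between chromosomes 1 to 22 and X, with the same chromosomes at its extremes in both replicates. Chromosome Y, with 1 and 2 peaks, was left out of this ranking. Chromosome 19 was densest, with 40.1 ± 0.685 peaks per Mb (mean ± SD, n = 2), followed by chromosome 22 with 34.1 ± 0.539, chromosome 20 with 33.4 ± 0.248 and chromosome 17 with 31.8 ± 0.593. Density was lowest on chromosome X, with 9.05 ± 0.0419 peaks per Mb, on chromosome 18, with 10.0 ± 0.535, and on chromosome 4, with 12.2 ± 0.0185 (n = 2 throughout). All peaks of chromosomes 1 to 22 and X divided by their summed span gave 21.0 peaks per Mb in each replicate. The median local expected pileup was highest on chromosome 8, at 1.57 and 1.66 times the median of all peaks, then on chromosome 20, at 1.46 and 1.40 times. Among chromosomes 1 to 22 and X it was lowest on chromosome 18, at 0.680 and 0.665 times, with chromosome X at 0.696 and 0.720 times and chromosome 4 at 0.708 and 0.701 times. Lengths were taken as the span from the first to the last peak.

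**Figure D3:**
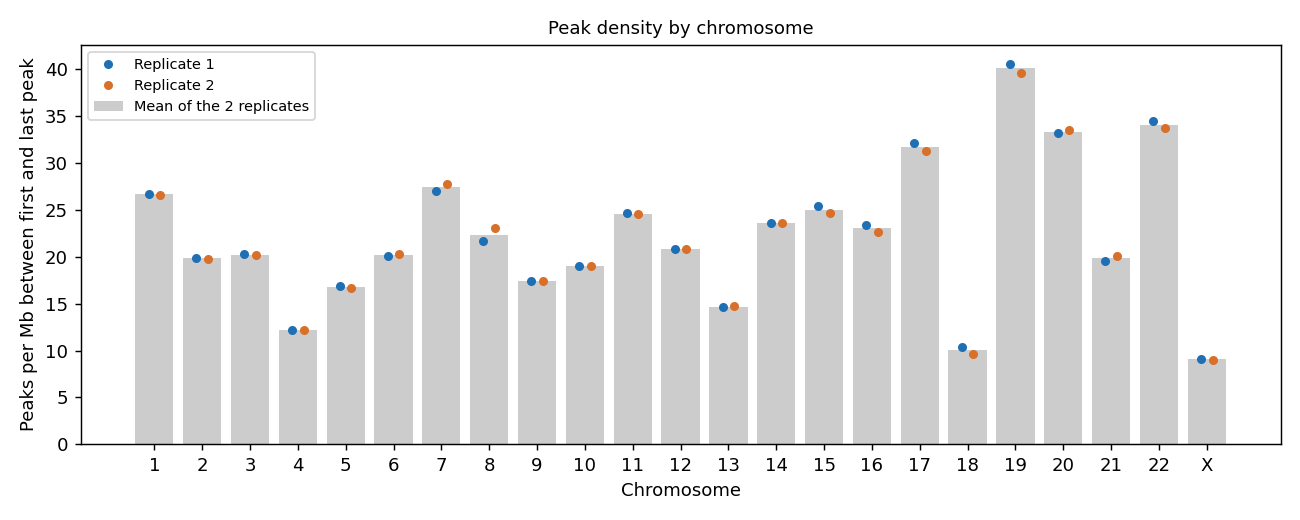
Peaks per Mb between the first and the last peak of chromosomes 1 to 22 and X, as the mean of the 2 replicates (bars) and for each replicate (points). Chromosome 19 is highest at 40.1 peaks per Mb and chromosome X lowest at 9.05.

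The single comparison that the design implies is that of replicate 1 with replicate 2, which asks how far the accessible regions of SKBR3 cells recurred between libraries. The lists were alike in size and shape, with 61782 and 61684 peaks that covered 31.1 and 31.3 Mb. Median peak width was 431 bases in replicate 1 (interquartile range 303 to 632) and 436 bases in replicate 2 (304 to 636). Median fold enrichment was 6.44 and 6.38. Median summit pileup was 20 and 23 fragments, higher in the deeper library.

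In replicate 1, 48362 of 61782 peaks (78.3%, Wilson 95% interval 78.0 to 78.6) overlapped a peak of replicate 2 by at least 1 base. In replicate 2 the count was 48353 of 61684 (78.4%, 78.1 to 78.7). These intervals cover counting error only. When one list was shuffled within chromosomes 100 times, on average 2.24% of either list was overlapped, and at most 2.38%. The overlap depended on peak strength. It was 27.2% and 30.0% in the 10% of peaks with the lowest −log10 q, and 99.97% and 99.95% in the 10% with the highest. The 13420 peaks found in replicate 1 alone were low and narrow, with a median pileup of 11 fragments and a median width of 284 bases against 25 fragments and 497 bases for shared peaks. The 13331 peaks found in replicate 2 alone had medians of 13 fragments and 284 bases against 28 fragments and 502 bases. A peak missing from one list at this depth is therefore not shown to be closed there. Inside the 13 bins of raised local expected pileup the overlap was 79.0% (76.4 to 81.4) in replicate 1 and 73.8% (71.1 to 76.4) in replicate 2, against 78.3% and 78.5% elsewhere.

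**Figure D4:**
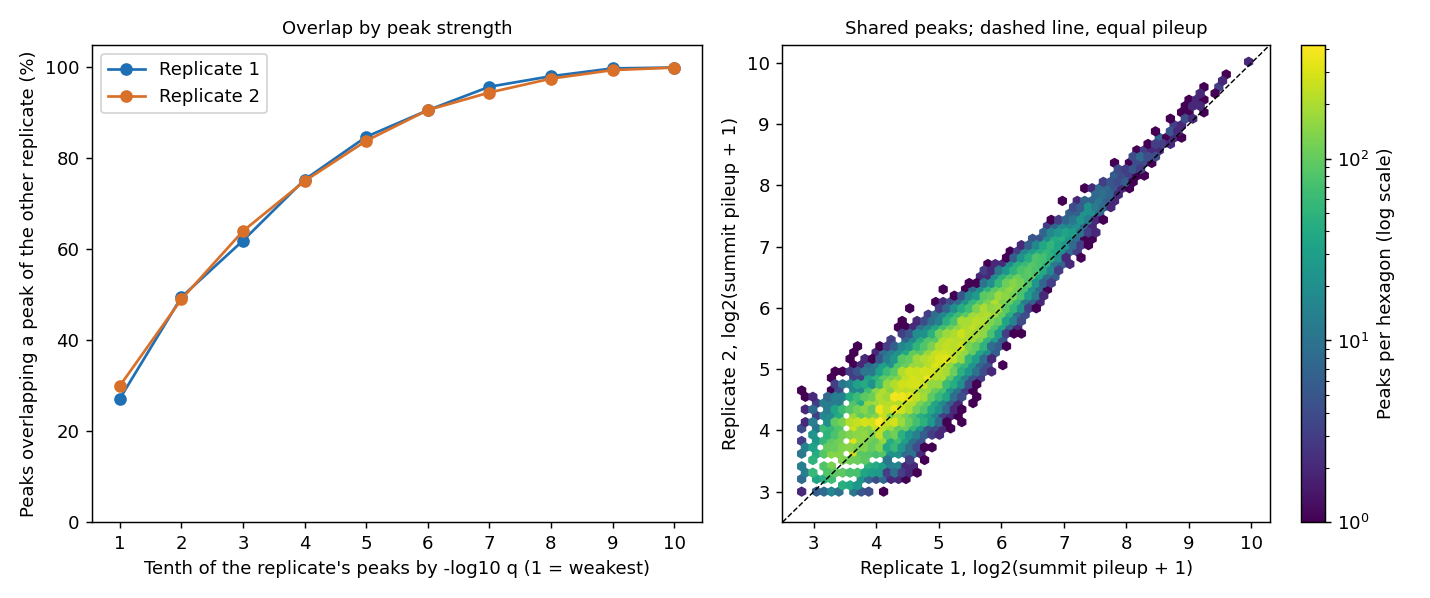
Left, share of each replicate's peaks that overlap a peak of the other replicate (percent), in 10 classes of −log10 q from weakest to strongest. Right, summit pileup of shared peaks in replicate 1 against replicate 2, as log2(pileup + 1), with colour for the number of peaks on a log scale; the share rises from 27.2% and 30.0% to 99.97% and 99.95%, and Pearson r is 0.933.

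Pileup at shared peaks was close between the replicates. Across the 47434 peaks that paired 1 to 1, Pearson r was 0.933 on log2(pileup + 1) and Spearman rho 0.919, while Spearman rho of the fold enrichment was 0.855. These correlations are across peaks, which are not independent replicates. Replicate 2 exceeded replicate 1 by a median factor of 1.11, or 0.15 on the log2 scale, with an SD of 0.35 between peaks. After centring on that median, 90.5% of the peaks agreed within a factor of 1.5 and 396 (0.835%) differed by more than a factor of 2. Summits lay a median of 39 bases apart, and 57.8% lay within 50 bases of each other. Below 15 fragments the variance of the standardised difference, which is 1 for independent Poisson counts, was 0.544. At 120 fragments or more it was 1.01. In simulated pairs of peaks, with the summit taken as the point of highest coverage, it was 0.804 to 0.921 in the first class and 0.912 to 1.02 in the last. These values cover only peaks called in both lists, which leaves out peaks that differed enough to be called in 1 list, so they do not measure the full difference between the libraries. Summed over whole chromosomes, the shared peaks differed between the libraries by more than counting error, the only error this test covers (chi-square 297, 22 degrees of freedom, p = 6.18e-50), and only 10 peaks had the same start, end and pileup in both lists. The lists are thus not copies of each other, and they were counted as 2 samples because the labels number them as replicates. Neither value shows that they came from separate cultures.

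The peaks with the largest differences had mean pileups of 18 to 28.5 fragments. The 5 shared peaks with the largest ratio in favour of replicate 2 included chromosome 10 from 123255316 to 123255560, with 11 fragments in replicate 1 and 38 in replicate 2, and chromosome 2 from 123439284 to 123439709, with 12 and 40. The others began at 41567965 and 96987632 on chromosome 1, with 9 and 29 and with 9 and 28 fragments, and at 124518355 on chromosome 4, with 11 and 35. In favour of replicate 1 the largest ratios were at chromosome 1 from 183149582 to 183150408, with 26 and 10 fragments, and chromosome 5 from 150439320 to 150439860, with 40 and 17. The rest began at 30818269 on chromosome 1, with 28 and 12 fragments, and at 40358754 on chromosome 3 and 70171333 on chromosome 17, each with 25 and 11. With 1 group of 2 libraries no residual degrees of freedom remain, so no test was made for single peaks and none of these differences is called.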

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

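The tests of raised bins, of overlap without those bins or in the upper part of pileup, and of bins without the 20 peaks of highest fold were chosen after the result was seen; the others were set before the data were examined. A stricter list, the upper 50% of −log10 q, held 30891 and 30846 peaks by construction, with median widths of 583 and 584 bases. The overlap was 71.1% and 71.2% with a reciprocal overlap of 50%, 84.3% and 84.5% in the upper 50% of −log10 q, and 84.8% and 86.7% in the upper 50% of pileup. It stayed within its interval on chromosomes 1 to 22 and X and without the raised bins. In the upper 50% settings both lists were cut first, so a peak whose partner fell under the cut counted as not overlapped. Against the whole other list, the overlap was already 90.6% in both replicates in class 6 of the 10 classes of −log10 q, and it rose with each stronger class. Pearson r was 0.975 without a log, 0.931 with a pseudocount of 0.1, 0.912 in the upper 50% of mean pileup and 0.934 after scaling to the same total. In the order chromosome 17 from 37 Mb, chromosome 8 from 124, 128 and 81 Mb, and chromosome 17 from 38 Mb, the fold over the median bin was 53.5, 32.0, 39.3, 25.4 and 25.9 in bins of 500 kb. By number of peaks it was 5.38, 5.09, 5.02, 5.34 and 5.14. With either replicate left out it ranged over 36.8 to 36.9, 26.4 to 28.2, 23.5 to 23.9, 22.9 to 24.3 and 19.2 to 19.2. Without the 20 peaks of highest fold the last bin gave 19.3, and the other bins moved by less than the spread between replicates. None of these 20 peaks lay in the bins named here. Their sums could not change, so this setting does not test how stable they are. Raised bins numbered 58 at 2-fold, 8 at 4-fold, 30 in bins of 500 kb and 6 from isolated peaks, and 13 to 15 from either replicate alone. All bins called from isolated peaks were among the 13, as were those at 4-fold, which holds by definition. At 2-fold 29 of the 58 lay off chromosomes 8 and 17, and in bins of 500 kb 2 of the 30. Density relative to all chromosomes in the stricter list was 2.08 for chromosome 19 and 0.372 for chromosome X, against 1.91 and 0.431. The cause of these shifts was not tested.

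Alternatives for promoter width, gene lists and gene background were not run, since no peak was assigned to a gene here. No paired analysis was possible because the series holds 1 group. Weak peaks recurred least, with 27.2% and 30.0% in the 10% of lowest −log10 q; whether depth is the cause was not tested.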

Other observations

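The first test of extra DNA copies and the comparison of the raised bins of chromosome 8 with its other bins were set before their results were seen; the other tests here were chosen after the result was seen, as were the runs of peaks named here. First tests of open chromatin density and of multi-copy sequences were replaced by those on segments left out, because the choice of bins bore on their outcome.

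Outside the raised bins of chromosomes 8 and 17, several of the longest runs of closely spaced peaks recurred in both replicates. Peaks no more than 10 kb apart formed a run of 23 on chromosome 16 from 1992002 to 2105165 in replicate 1, and of 16 from 1993201 to 2073651 in replicate 2. Chromosome 10 carried a run of 17 peaks from 80971004 to 81059706 in replicate 1, with 17 from 80954939 to 81059313 in replicate 2. A second run there had 16 peaks from 79585847 to 79668091 and 17 from 79578772 to 79668244. On chromosome 11 the run from 126223528 to 126276093 held 14 peaks in replicate 1, and that from 126203129 to 126276170 held 20 in replicate 2. On chromosome 15 a run of 14 peaks from 41099269 to 41171344 had 15 from 41099254 to 41171344 in replicate 2. Others were among the longest in a single replicate, such as runs of 17 peaks on chromosome 3 from 50297289 in replicate 1 and from 13492971 in replicate 2. By number of peaks the bin of chromosome 20 from 48 to 49 Mb ranked 1 and 2, with 100 and 104 peaks. Other dense bins were chromosome 11 from 65 to 66 Mb, with 93 and 98 peaks, and chromosome 19 from 45 to 46 Mb, with 92 and 87.

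The local expected pileup was raised over 13 bins of chromosomes 8 and 17, and a dense run of open sites inside the 10 kb window might raise it. Bins were picked on every other 100 kb segment, and isolated peaks were then taken from the segments left out. They had 4.01 times the local expected pileup of isolated peaks elsewhere in replicate 1 (bootstrap 95% interval 3.56 to 4.46, 186 peaks). In replicate 2 the ratio was 4.09 (3.49 to 4.55, 179 peaks). Both lay above the highest of 10000 random draws of isolated peaks elsewhere, 1.24 and 1.23. Other called peaks within 10 kb thus did not account for the rise at these peaks. The draws were scattered, whereas the left-out peaks lay in a few stretches, beside the segments used to pick the bins. The draws therefore do not measure how far neighbouring peaks of 1 stretch vary together. A call at isolated peaks of the raised bins needed a median of 18 and 21 fragments. Lower open sites could therefore lie uncalled in the window, and dense open chromatin is not excluded. Reads piled on a few multi-copy sequences would leave neighbouring segments at ordinary levels, yet 95.4% and 95.6% of the peaks in the segments left out lay above the median of all peaks. Extra DNA copies of these stretches remain an open hypothesis: the summit pileup of isolated peaks was 1.59 (1.41 to 1.88) and 1.70 (1.5 to 1.85) times that elsewhere, but against isolated peaks elsewhere drawn above the caller's limit at the same local expected pileup the ratio was 0.818 in replicate 1 (median 27 fragments, with 95% of draws from 30 to 36) and 0.944 in replicate 2 (34, with 33 to 40). Isolated peaks were thus lower than the draws in replicate 1 and within them in replicate 2. The caller's limit may account for their height over peaks elsewhere. Their local expected pileup was 4.22 and 4.47 times that elsewhere, though the choice of bins bore on this ratio. With the summit pileup it met the prediction set beforehand for extra copies, at least 1.5 for both values in both replicates. The draws were taken at a local expected pileup that extra copies would also raise, so they cannot decide. No group in the design gives copy number.

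The 20 shared peaks of highest fold were narrow for their pileup, with a median width of 561 bases against 850.2 for sets matched on pileup, though wider than the median peak of either list, 431 and 436 bases, and they included chromosome X from 108297395 to 108297828, with fold 32.5 and 30.7. A peak's own fragments enter its local expected pileup, and across 1859 isolated shared peaks of at least 60 fragments fold fell with width (Spearman rho −0.489, across peaks), but this restates the pattern, so the caller's window cannot be told apart from other causes of the width. If coverage is assumed to fall evenly from summit to ends, own fragments made up a median of 72.1% of the local expected pileup at the 20 peaks and 64.7% at the 1859, an estimate that decides nothing. Their ends differed between the replicates by a median of 10.5 bases, with 1 end shifted by 292, against a median of 28.5 in sets matched on pileup and width. The cause of the close ends was not tested, and no biological explanation was tested. Blacklist filtering is not given, so at these 20 peaks too, fragments from multi-copy sequences cannot be told apart from open chromatin.

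The ratio of replicate 2 to replicate 1 differed between chromosomes, with centred medians on the log2 scale from −0.06 on chromosomes 19 and 22 to 0.05 on chromosome 8. Counting noise is excluded as the whole cause of the difference between these libraries (chi-square p = 6.18e-50). A library bias that follows peak density may contribute, with Pearson r −0.486 over 23 chromosomes (permutation p = 0.0183, adjusted 0.0367 over 4 relations) and Spearman rho −0.428 (permutation p = 0.0423, adjusted 0.0564), but it rests on chromosomes 19 and 22, without which r was −0.144 (permutation p = 0.535, adjusted 0.535), while without chromosome 8 it was −0.540 (permutation p = 0.00968, adjusted 0.0367). A copy number difference in the raised bins of chromosome 8 cannot be told apart from none for those bins, which exceeded its other bins by 0.0253 on the log2 scale (bootstrap 95% interval −0.000826 to 0.0602, 9 against 123 bins, permutation p = 0.475), and the raised bins of chromosome 17 exceeded its other bins by 0.0394 (0.0235 to 0.0737, 4 against 74 bins, permutation p = 0.372; both adjusted p = 0.475 over 2 comparisons). Such a difference in the raised bins of chromosome 8 leaves unexplained its other 123 bins, which exceeded all shared peaks by 0.0406 (0.0202 to 0.0621), and no biological explanation was tested, since the design has 1 group.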
